A study of Homo sapiens with 4 samples.

How the data were processed

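Expression in A549 and WI38VA13 cells was measured on 4 two-colour arrays of 3 kinds of chip, and the labels state that RNA of 1 sample per cell line was used. Per the labels' protocols, 30 µg of total RNA per channel was copied into cDNA from oligo-dT primers, and a Cy3- or Cy5-coupled nucleotide was built in. For the Takara chip and the LC-sense DNA chip, spot intensities of each dye, with local background and its SD, were used as deposited, per the file headers, with no normalization. The scanner and its settings are not given in the sources used here. For every array a value table deposited by the authors gives 1 log2 ratio per spot or feature, with scale, centring and direction unstated. For the Takara chip and the LC-sense DNA chip these were found by setting each table against the scanner values. The Takara table was log2 of Cy5 over Cy3 after background subtraction (r = 0.998 over 825 spots) plus a constant of 1.26, with a median of −0.44. The table of the LC-sense DNA chip was log2 of Cy3 over Cy5 with no constant (r = −0.999 against the opposite ratio, over 339 spots), with a median of 0.52, and thus runs opposite to the Takara table. For the LC-sense 5K arrays no scanner values were used. Their medians were 0.08 for the original and −0.08 for the dye-swapped array, the numerator of the ratio and the base of the logarithm stay unknown, and base 2 was assumed from the other tables. The planned check of their direction against the Takara chip over shared genes was not possible because features have numbers and no names there.

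Scanner values were background-corrected with the normexp method (offset 50) and normalized by loess of the log ratio on mean intensity within each array (span 0.3, 4 iterations), in limma 3.58.1 under R 4.3.3. Control spots entered the background model and had weight 0 in loess. A spot was above background where its mean signal exceeded the local background by over 2 background SDs. A gene was kept where it was above background in at least 1 channel. A gene above background in 1 channel has only a bound, given as at least N-fold. It is the normalized log2 value of the bright channel less the higher of 2 values, the lowest normalized value among spots above background in the dim channel and the gene's own. Where the gene's own value is the higher, the bound equals the measured fold, and the text says so. The spot's own detection limit, which can be higher, did not enter, so the true fold can be smaller than the bound. The bound therefore belongs to the main setting, and other settings or the other chip can give smaller or opposite ratios. As dyes were not swapped on these 2 chips, dye bias of single genes is not removed from their ratios. The offset and the background model compress ratios of dim spots. Replicate spots were averaged, and no gene had several different probes. The LC-sense 5K arrays were centred on their medians, the sign of the swapped array was turned, and both were averaged to 1 value.

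Genes were named through the RefSeq gene table of GRCh38.p14, used for names alone. On the Takara chip 642 of 985 spots carried an accession and 547 matched that table, 4 more shared a name with a matched spot, and 69 were named by hand from an unambiguous full gene name in the file. The LC-sense DNA chip gave names only, of which 203 spots shared a name with a matched Takara spot and 81 were named from a full name. Other spots kept the file's name, 307 of them unnamed clones of the Takara chip. No coordinates are given, because the sources used here name no genome build.

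With 1 RNA sample per line, no test was run and genes were called by size, at 2-fold or more. Technical error was taken from replicate spots and from the dye swap. The background correction, scaling, filter, threshold, 20 gene lists, rule for named genes and all but 3 of the alternatives were fixed before the data were examined. The intensity bins, the number of resamples and the names taken by hand were set during the analysis. A first calculation filtered single spots before averaging and was replaced, after its results had been seen, by the planned filter on genes, which left the 2-fold counts as they were. The rule took genes with a symbol. These were the 10 largest ratios of each direction on the Takara chip, the 6 largest on the LC-sense DNA chip, the 2 largest members of each list in each direction on each chip, the 6 largest means in each direction among genes 2-fold apart on both named chips, and at most 2 features of each direction on the LC-sense 5K chip. Other genes named in the text, such as KRT19 and TNFAIP6 across chips, were chosen after their values were seen. The values of some genes are not reported here. A list with at least 3 measured genes was set against 10000 random lists of the same size drawn within 5 bins of mean intensity, and a percentile at or beyond 2.5 or 97.5 counted as standing apart. Random lists describe these arrays and are no test of the cell lines. The LC-sense 5K chip could not enter gene lists or comparisons between chips.

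The normalization was tested on simulated data with the intensities of each chip, run on 941 and 304 gene spots. On the simulated Takara chip 85.0% of spots with a true 3-fold difference and 86.7% with a true 4-fold difference passed 2-fold, 0% of unchanged spots did, and all planted directions were recovered. On the simulated LC-sense DNA chip these shares were 95.8%, 100% and 0%. For planted 2-fold differences they were 0% on the Takara chip and 33.3% on the LC-sense DNA chip. Unchanged spots had an SD of 0.15 on the simulated Takara chip and 0.14 on the simulated LC-sense DNA chip. Real replicate spots had 0.14 and 0.25. Uneven signal across the slide was not simulated. At this noise unchanged spots could hardly pass 2-fold, so the 0% is no rate of false calls on the real chips. Lists were simulated apart from the chips' data, on 600 and 280 invented genes with independent random ratios unrelated to intensity. Of lists with no difference, 5.5% and 6% fell beyond the outer percentiles. That design sets these shares in advance, so they check the calculation and do not describe lists of real genes. The number of arrays limits the precision. Alternatives covered the background correction, the scaling, the filter on dim spots, the threshold, the deposited tables, single arrays of the dye swap and the matching of random lists. As an alternative, the deposited tables were turned to A549 over WI38VA13 and centred on the median of the gene spots, and were also used without centring. Added after seeing the data were the use without centring, loess within each sub-grid and the Takara chip without the first 6 rows of its first sub-grid. Calculations outside limma used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.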

Results

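Gene expression was compared between A549, a human lung adenocarcinoma cell line of epithelial origin, and WI38VA13, a line of human lung fibroblasts transformed with simian virus 40. RNA of 1 sample of each line was labelled with Cy3 or Cy5 and hybridised together to 4 two-colour arrays of 3 kinds of chip. A549 was labelled with Cy5 and WI38VA13 with Cy3 on the Takara chip, on the LC-sense DNA chip and on the original array of the LC-sense 5K chip, and the dyes were exchanged on the second LC-sense 5K array. The arrays are therefore repeat hybridisations of 1 RNA pair. No test across the cell lines was possible, no p-value is given, and the errors stated are technical. Ratios are written as log2 of A549 over WI38VA13, so that positive values stand for higher signal in A549.

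The Takara chip held 941 gene spots, of which 613 were above background in at least 1 channel, 404 of them in both. These gave 588 genes. Median signal over local background was 1.26 in the Cy3 channel and 1.47 in the Cy5 channel. The LC-sense DNA chip was smaller and brighter. Of its 304 gene spots, 265 were above background in both channels, 281 genes were measured, and median signal over background was 2.66 in Cy3 and 5.72 in Cy5. The spread between replicate spots of 1 gene on the log2 scale was 0.14 on the Takara chip (pooled SD, 35 spots of 8 genes) and 0.25 on the LC-sense DNA chip (pooled SD, 22 spots of 5 genes). Most other genes had 1 spot and so no error of their own. The LC-sense 5K chip gave ratios for 4995 features on both of its arrays.

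On the Takara chip, genes of keratins and epithelial cell contacts were higher in A549, and genes of collagens and other extracellular matrix proteins were lower. All 7 measured genes of the list of epithelial junction and keratin genes had positive ratios, with a median of 1.07, and 5 of them had ratios past 2-fold, 2 of these with bounds below it. SPINT2, a membrane-bound serine protease inhibitor of epithelia, was 2.78-fold higher, and the keratin gene KRT7 was 2.35-fold higher. KRT19 and ITGB4 were not above background in WI38VA13 and were at least 1.80-fold and at least 1.61-fold higher. KRT8 was 2.25-fold higher. With the genes not above background in WI38VA13 set to their bounds, the list median was 0.84. Of the 15 measured genes of the list of fibroblast and extracellular matrix genes, 8 had ratios past 2-fold on the WI38VA13 side, of which TIMP3 had a bound of 1.99-fold, none was 2-fold higher in A549, and the median log2 ratio was −1.02 (−0.99 with 5 genes at their bounds, and −1.76 with the local background subtracted). COL1A2, a chain of type I collagen, was 3.57-fold lower in A549. CCN1, a matrix-associated signalling protein, was 3.64-fold lower, and VIM, the intermediate filament protein of mesenchymal cells, was 3.29-fold lower. COL6A3, a chain of type VI collagen, and TNC, which encodes tenascin C, were not above background in A549 and were at least 3.25-fold and at least 3.50-fold lower. In the deposited value table VIM was at −0.94 after centring on the table's median and past 2-fold without it. With no background correction COL6A3 was under 2-fold, at −0.82. The epithelial list lay at percentile 100 and the matrix list at percentile 0 of 10000 random lists of the same size and intensity. These percentiles describe this array only.

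Of the genes with the largest measured ratios on the Takara chip, several have only bounds, which do not rank them. LCK, RARB, TNFAIP6, IL1A and BIRC3 were above background in A549 and not in WI38VA13. RARB, a retinoic acid receptor gene, was at least 4.19-fold higher in A549. TNFAIP6, which encodes a hyaluronan-binding secreted protein, was at least 3.65-fold higher, and BIRC3, an inhibitor of apoptosis, was at least 2.72-fold higher. The bounds were 2.37-fold for LCK, a lymphocyte kinase, and 2.34-fold for the cytokine gene IL1A. IGFBP2, a binding protein of insulin-like growth factors, was 5.36-fold higher, EPHA2, a receptor tyrosine kinase, was 3.01-fold higher, and IFI30, a lysosomal thiol reductase, was at least 2.35-fold higher. The spots of these 8 genes, and those of COL6A3 and KRT8, lay in the first 6 rows of the first sub-grid, where background in the Cy5 channel was 262.5 intensity units (median) against 137 elsewhere. ABCC3, an organic anion exporter, was 3.16-fold higher in A549 and lay outside those rows. Lower in A549 were SERPINB2, an inhibitor of plasminogen activators, by 2.89-fold, the G protein subunit gene GNAI2 by 2.76-fold, and GAS6, a ligand of receptor tyrosine kinases, by 2.65-fold. SERPINB2 was not above background in A549, and its bound equals its measured fold. MYBL2, a transcription factor of proliferating cells, was 2.42-fold lower and ALDOA, the glycolytic aldolase, was 2.38-fold lower. With no background correction GAS6 (−0.93), MYBL2 (−0.95) and IFI30 (0.99) were under 2-fold, and in the deposited value table ALDOA was, with centring on its median (−0.38) and without (−0.84), as was MYBL2 with centring (−0.73).

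**Figure D1:**
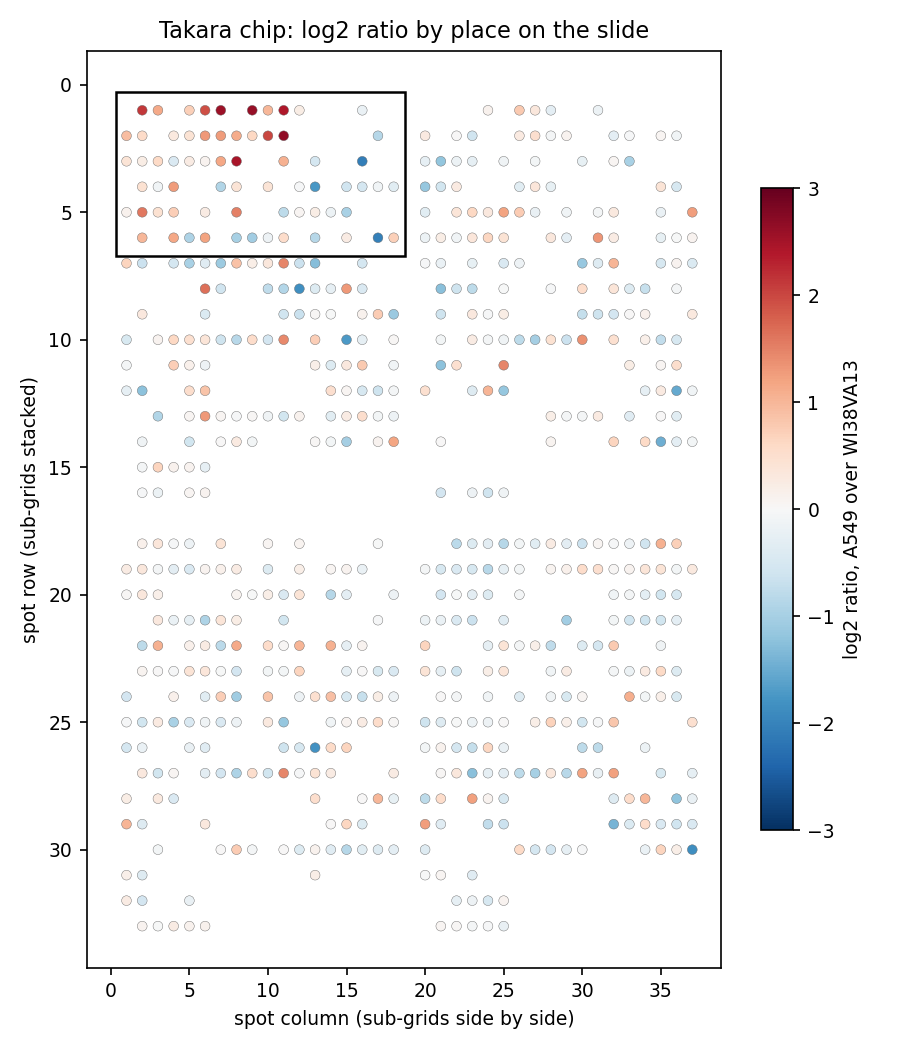
Each point is a gene spot of the Takara chip that was above background in at least 1 channel, drawn at its row and column on the slide (sub-grids side by side and stacked) and coloured by its log2 ratio of A549 over WI38VA13. The box marks the first 6 rows of the first sub-grid, which hold 20 of the 43 genes with ratios past 2-fold on the A549 side.

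In all, 43 of 588 genes on the Takara chip had ratios of at least 2-fold on the A549 side and 27 on the WI38VA13 side. Of these 70 genes, 23 were above background in a single channel, 11 of them higher in A549 and 12 higher in WI38VA13, and the bound itself was over 2-fold for 12. Of 16 control spots taken as negative by name, 8 also passed the filter in Cy3, among them 4 of 4 lambda-A and 3 of 4 lambda-B spots. Cy3 is the channel that alone admitted 195 gene spots and on which the bounds for lower genes rest. The first 6 rows of the first sub-grid held 20 of the genes higher in A549 and 4 of those higher in WI38VA13, and without these rows the counts were 23 and 23. Which line had more genes on its side depended on the scaling. With the array median in place of loess, 20 genes were higher in A549 and 46 higher in WI38VA13, a share of 30.3% on the A549 side against 61.4%, and the median of all genes moved from −0.04 to −0.20. With loess run within each sub-grid the counts were 35 and 33, and with the local background subtracted they were 54 and 74. The deposited value table gave 106 and 78 after centring on its median and 50 and 141, a share of 26.2%, without. In simulated data on the intensities of this chip, planted 2-fold differences came out at a median log2 ratio of 0.76, with 0% past the threshold, and planted 4-fold differences came out at 1.77.

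Further gene groups stood apart on the Takara chip. All 4 measured genes of the list of NRF2 target and xenobiotic metabolism genes had positive ratios (median 1.02, percentile 99.9 of random lists), although TXNRD1, at 0.29, turned to −0.07 with the array median in place of loess. They included ABCC3, and GSTP1, a glutathione transferase, had a ratio of 0.67. All 5 measured glycolysis genes had negative ratios (median −0.69, percentile 0.615), 2 of them past 2-fold, although GAPDH (0.31) and LDHA (0.36) turned positive in the deposited value table centred on its median. PGK1, which encodes phosphoglycerate kinase, was 2.08-fold lower after ALDOA. In the housekeeping list, 3 of 8 genes were at least 2-fold lower in A549 and the median was −0.68 (percentile 0.13). EEF1A1, a translation elongation factor, was 2.35-fold lower and TUBA1A, an alpha-tubulin, was 2.08-fold lower. ACTB had a log2 ratio of −0.68 ± 0.09 (SD, 4 spots) and GAPDH one of −0.69 ± 0.12 (SD, 4 spots), but in the deposited value table both had 0.31 after centring on its median and −0.15 without. PGK1 (−0.90), EEF1A1 (−0.99) and TUBA1A (−0.54) were under 2-fold there without centring, and also with it. PGK1 was also under 2-fold with no background correction (−0.90) and with loess run within each sub-grid (−0.94). The housekeeping and glycolysis lists share GAPDH and PGK1. Of 5 measured p53 target genes, 4 had positive ratios and none reached 2-fold (median 0.68, percentile 98.8, and 1.03 with the local background subtracted). TNFRSF10B, a death receptor, had a log2 ratio of 0.87 and BTG2, an antiproliferative gene, one of 0.77. In the cytokine and chemokine list, 3 of 8 genes were at least 2-fold higher in A549 (median 0.45, percentile 99.2, and 0.39 with 5 genes at their bounds), with AREG, a ligand of the epidermal growth factor receptor, 2.75-fold higher, or 0.84 on the log2 scale with no background correction. Without the first 6 rows of the first sub-grid, which hold IL1A, that list's median was 0.11 at percentile 84.3.

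Other lists did not stand apart from random lists on the Takara chip. Of 19 measured genes of cell cycle and DNA replication, 14 had negative ratios (median −0.18, percentile 7.95). RFC4, a clamp loader subunit, was 1.85-fold lower, which is also its bound, with A549 not above background. Among 14 apoptosis regulators, BIRC3 was the 1 gene past 2-fold (median 0.06, percentile 79.5). MCL1, in the rows named above and with A549 not above background, was 1.89-fold lower, which is also its bound. Its direction turned with no background correction (0.16), so it is not settled. Of 9 genes of growth factor receptors and RAS-MAPK signalling, EPHA2 and FGFR4 were at least 2-fold higher in A549, the latter by 2.46-fold (median −0.07, percentile 37.9). Of 7 interferon and antigen presentation genes, IFI30 and IFIT1, both in those rows, were at least 2-fold higher (median −0.07, percentile 43.5). Among 9 proteases and inhibitors, MMP7 and PLAU were 2.29-fold and 2.03-fold higher in A549, while PLAT was at least 1.95-fold lower after SERPINB2 (median −0.01, percentile 52.0). None of 11 integrin and adhesion genes was 2-fold apart (median 0.11, percentile 78.5). ITGB5 had the highest ratio of them, 0.79, and VCL the lowest, −0.46. Signs of some medians turned with the scaling. The integrin median was −0.19 with the array median in place of loess and −0.02 with loess within each sub-grid. The apoptosis median was −0.03 and −0.05 under these settings. The interferon median was 0.15 with loess within each sub-grid. With genes above background in 1 channel at their bounds, medians were −0.12 for the cell cycle, −0.04 for growth factor receptors, and 0 for apoptosis regulators and for interferon genes. With the array median in place of loess, IFIT1 (0.73), PLAU (0.66) and, by a small margin, MMP7 were under 2-fold, and with no background correction IFIT1 (0.96), FGFR4 (0.82), MMP7 (0.50), PLAU (0.57) and PLAT (−0.65) were. IFIT1 also was with loess run within each sub-grid (0.67).

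**Figure D2:**
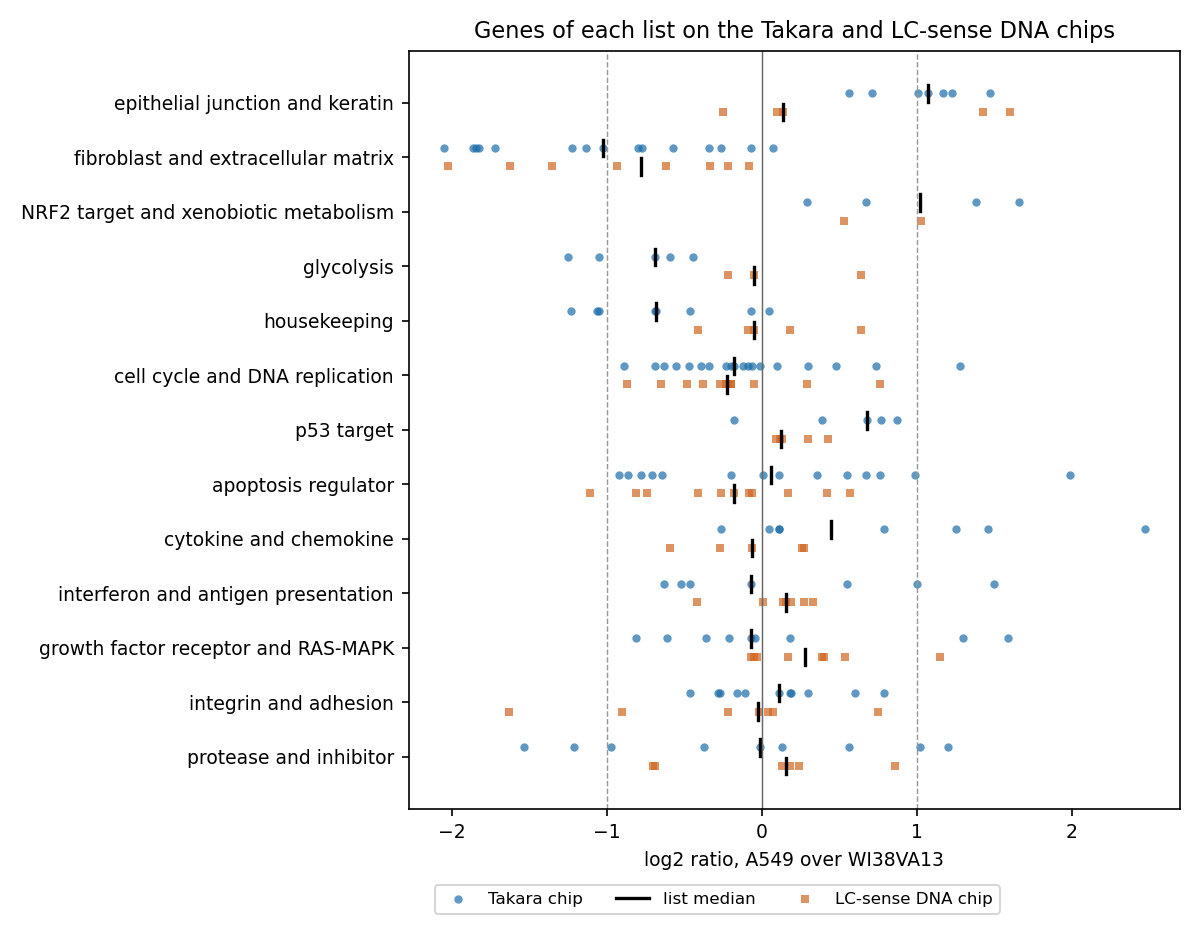
Each point is the log2 ratio of A549 over WI38VA13 of a gene in the named list, with circles for the Takara chip and squares for the LC-sense DNA chip. Genes with only a bound are drawn at their measured ratio. Black bars are list medians where at least 3 genes were measured, and dashed lines mark 2-fold. On the Takara chip the 7 epithelial genes lie between 0.56 and 1.47, and 14 of the 15 fibroblast and matrix genes lie below 0.

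The LC-sense DNA chip also showed matrix genes lower in A549 and part of the epithelial genes higher. Its ratios were taken from the scanner values in the direction given by the dye labels, which is opposite to the deposited value table of this chip (r = −0.999 over 339 spots). All 8 measured fibroblast and matrix genes had negative ratios (median −0.78, percentile 0.01 of random lists), and 3 were at least 2-fold lower in A549. COL3A1, a chain of type III collagen, was 4.05-fold lower, COL6A3 was 3.08-fold lower, and MMP2, a gelatinase, was 2.55-fold lower. In the epithelial list, KRT8 was 3.03-fold higher in A549 and SPINT2 was 2.70-fold higher, while KRT7 had a log2 ratio of −0.25, which turned to 0.05 with the array median in place of loess, and the list did not stand apart (5 genes, median 0.14, percentile 62.7). APRT, a purine salvage enzyme, was 2.89-fold higher. FHIT, a tumour suppressor of the histidine triad family, was 2.39-fold higher, and the transcription factor gene JUNB was 2.22-fold higher. DRG2, a GTP-binding protein gene, was 2.13-fold higher. Lower in A549 were SDC1, a heparan sulfate proteoglycan, by at least 2.80-fold, CDKN2C, an inhibitor of cyclin-dependent kinases, by 2.66-fold, and the inflammatory caspase gene CASP1 by 2.16-fold. The caveolin gene CAV1, the 1 measured gene of the lung epithelial list, was 2.13-fold lower (−0.76 on the log2 scale with the array median), and had a log2 ratio of −0.91 on the Takara chip, in the first 6 rows. With no background correction SDC1 (−0.80), CASP1 (−0.61), FHIT (0.78) and DRG2 (0.90) were under 2-fold. FHIT also was with loess run within each sub-grid (0.97) and in the deposited table not centred (0.85), and CAV1 was in that table after centring (−0.73).

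On this chip 7 of 281 genes were at least 2-fold higher in A549 and 7 were at least 2-fold lower. With the array median in place of loess, 13 were higher in A549 and 8 lower, a share of 61.9% on the A549 side against 50%, and the deposited value table, with its sign turned, had 13 higher and 23 lower after centring on its median (36.1%) and 4 higher and 66 lower without (5.71%). Besides the matrix genes, no list lay beyond the outer 2.5% of random lists. The 12 cell cycle and DNA replication genes had a median of −0.22 (percentile 6.50), with RFC4 at −0.65 and BRCA1 at 0.76. The BRCA1 spot was brighter here than that of ALDOA (mean log2 intensity 15.6 against 15.1). On the Takara chip it was far dimmer (8.20 against 12.7). The cause was not tested, so the BRCA1 ratio is uncertain. The 8 genes of growth factor receptors and RAS-MAPK signalling had a median of 0.28 (percentile 95.4, and 98.2 with loess run within each sub-grid). The 11 apoptosis regulators had a median of −0.18 (percentile 13.1), with DAP at −0.81 and DAPK1 at 0.57. Medians were 0.13 for 5 p53 targets (percentile 69.4), 0.16 for 7 interferon and antigen presentation genes (percentile 79.8), −0.06 for 5 cytokines and chemokines (percentile 31.8), −0.02 for 7 integrin and adhesion genes (percentile 40.1) and 0.16 for 6 proteases and inhibitors (percentile 77.7). The array median in place of loess turned the sign for protease (−0.29), interferon (−0.06) and integrin genes (0.09). With genes at their bounds the cytokine, integrin and protease medians were 0. The 3 glycolysis genes and the 5 housekeeping genes each had a median of −0.05, at percentiles 37.6 and 35.6. Both medians are the value of GAPDH, which was above background in A549 in 1 of its 4 spots. Its mean log2 intensity was 7.64 here against 13.7 on the Takara chip, so this ratio and both medians are uncertain. ACTB had −0.41 ± 0.23 (SD, 8 spots) and ALDOA −0.22. With the array median in place of loess the glycolysis median was −0.31 and the housekeeping median turned to 0.04. PGK1 had a ratio of 0.64 on the LC-sense DNA chip and −1.05 on the Takara chip. Both measured NRF2 target and xenobiotic metabolism genes had positive ratios, 1.03 for ABCC3 and 0.53 for TXNRD1.

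Markers of other cell types were few among the measured genes. The Takara chip named 6 genes of the blood and immune cell list, of which only 1 was above background. It named 3 of the endothelial list, and none was above background. In the blood and immune cell list, LCK was measured on the Takara chip with the bound given above, and on the LC-sense DNA chip LYZ had a ratio of −0.18, or 0.10 with the array median in place of loess. CD34 and KDR, the latter of the endothelial list, were not above background in A549 there. CD34 was 1.30-fold lower, which is also its bound, and KDR was at least 1.11-fold lower. Of cytosolic ribosomal protein genes, RPSA had a ratio of −0.32 on the LC-sense DNA chip. No gene of the plasma protein list was named on these chips, and the 1 named gene of the neural cell list was not above background. CDKN2A, CDKN2B and MTAP, which are reported as lost in A549, were not named on either chip and so did not check the labels.

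The 2 chips with gene names shared 165 measured genes. Their log2 ratios correlated across genes with r = 0.61 (95% interval 0.50 to 0.70) and Spearman's rho = 0.59, where genes are not independent replicates, and 72.1% of the genes had ratios of 1 sign on both. In total, 7 genes were at least 2-fold apart on both chips, each in the same direction on both. A549 was labelled with Cy5 on both chips, so a dye bias of single genes could add to this agreement. The mean log2 ratio of both chips was 1.45 for SPINT2, 1.39 for KRT8, 1.38 for APRT, 1.35 for ABCC3, 1.21 for DRG2 and −1.19 for MMP2, and COL6A3 was at least 3.25-fold lower on the Takara chip and 3.08-fold lower on the other. On 1 of the chips APRT was under 2-fold with the array median in place of loess (0.99, Takara), and DRG2 was with loess run within each sub-grid (0.75, LC-sense DNA). With no background correction DRG2 (0.45) and MMP2 (−0.74) were under 2-fold on the Takara chip and ABCC3 (0.93) and DRG2 (0.90) on the LC-sense DNA chip. In the deposited value tables MMP2 was, on the Takara chip after centring (−0.85), and ABCC3 (0.92) and DRG2 (0.88) were, on the LC-sense DNA chip without it. Of the 18 shared genes past 2-fold on the Takara chip, 15 had a ratio of the same sign on the LC-sense DNA chip. All 11 past 2-fold on the LC-sense DNA chip had the same sign on the Takara chip. Of these 11, FHIT had 0.22 on the Takara chip with A549 not above background, and SDC1 had −0.11. Both turned sign in the deposited Takara table centred on its median (−0.13 and 0.11). The SD of the difference between the chips was 0.54, which is larger than the spread between replicate spots on either. TNFAIP6 had a ratio of 0.21 on the LC-sense DNA chip, or −0.05 with loess run within each sub-grid, against at least 3.65-fold higher in A549 on the Takara chip, and IGFBP2 had 0.82 against 2.42. SDC1 was at least 2.80-fold lower on the LC-sense DNA chip and had −0.11 on the Takara chip. The receptor genes EGFR and AXL were not above background in A549 on the Takara chip. They were 1.52-fold and 1.75-fold lower there, which are also their bounds. On the LC-sense DNA chip, above background in both channels, they had ratios of 0.40 and 0.54, so their direction is not settled.

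**Figure D3:**
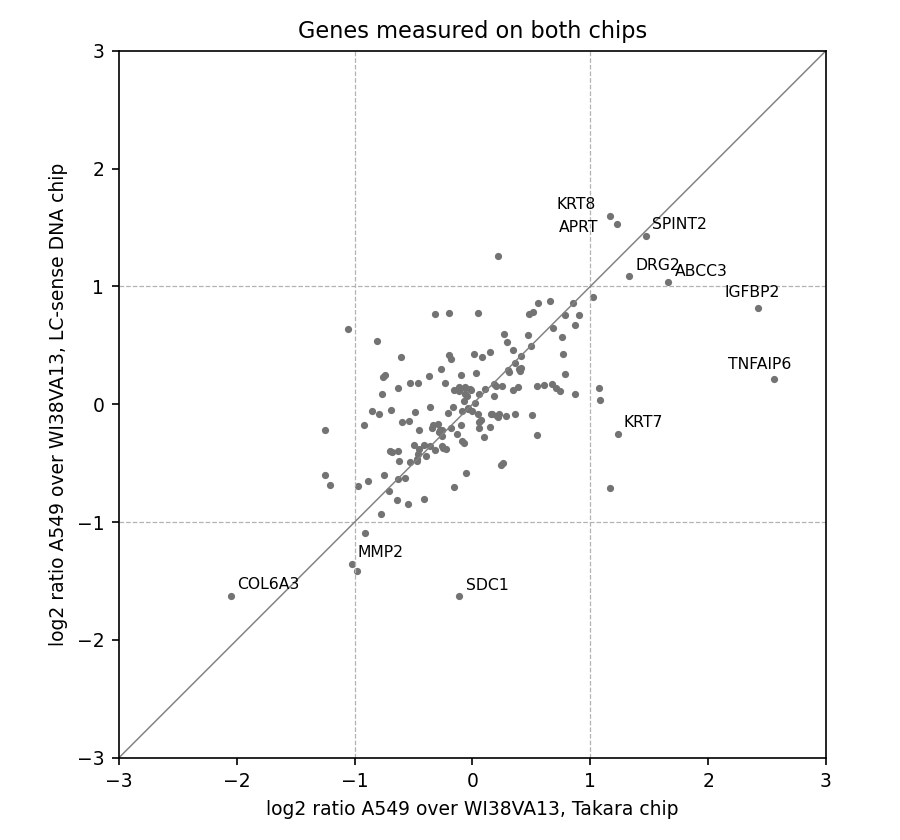
Each point is 1 of 165 genes measured on both chips, with its log2 ratio of A549 over WI38VA13 on the Takara chip (horizontal) and on the LC-sense DNA chip (vertical). The solid line marks equal ratios and the dashed lines mark 2-fold, and 7 genes lie past 2-fold on both. Genes with only a bound are drawn at their measured ratio.

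On the LC-sense 5K chip the direction of the ratios could not be settled and its features carry no gene names in the files used, so sizes and counts are given without a cell line. The logarithm was taken to be of base 2, as in the value tables of the other chips. The deposited ratios of the original and dye-swapped arrays mirrored each other (r = −0.950 across 4995 features). After the sign of the swapped array was turned and each array centred on its median, r was 0.950 (95% interval 0.947 to 0.953) and rho was 0.87. The SD of the mean of both arrays was 0.93 across features and that of each array's deviation from this mean was 0.15. At least 2-fold differences of 1 direction on both arrays were found for 720 features (14.4%), of which 277 were positive on the original array and 443 negative. At 4-fold these counts were 81 and 150, and at 8-fold 37 and 45. Of 1010 features past 2-fold on either array, 1000 had the same sign on both and 1 was past 2-fold in opposite directions. Feature 1490 had the highest mean log2 ratio, 6.04, followed by feature 4248 with 5.46, and on the other side features 4636 and 4070 had −5.70 and −4.89.

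**Figure D4:**
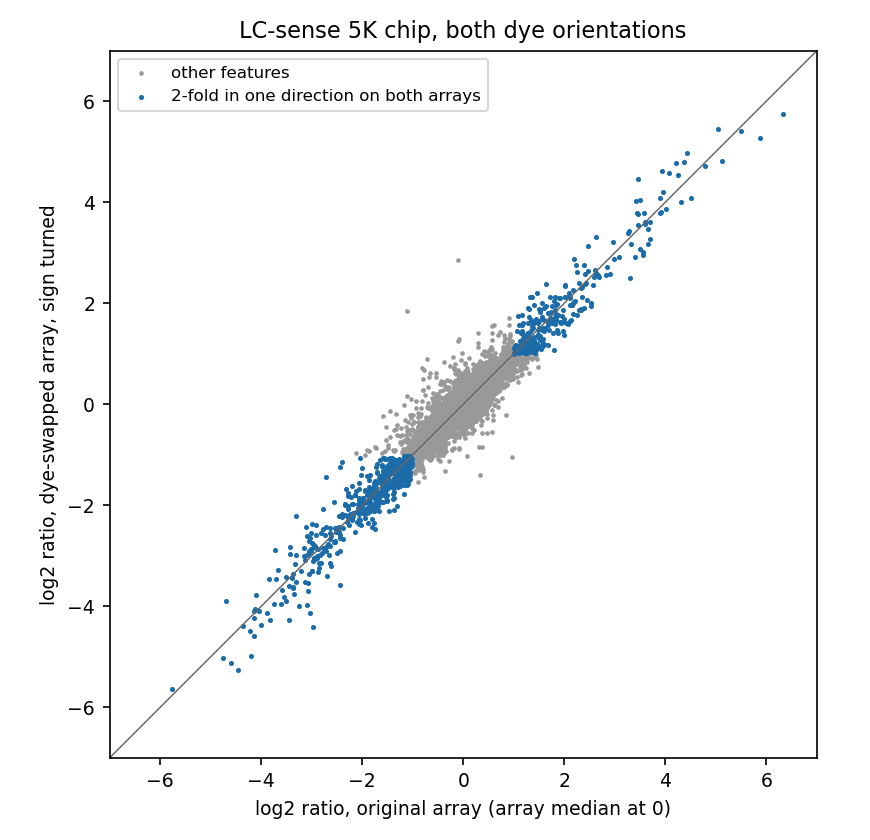
Each point is 1 of 4995 features of the LC-sense 5K chip, with its log2 ratio on the original array (horizontal) and on the dye-swapped array with the sign turned (vertical), each centred on the array median. The 720 features at least 2-fold apart in 1 direction on both arrays are drawn in blue, and the line marks equal ratios.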

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

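Chosen after the result was seen, in whole or in part, were the tests of uneven signal and of a true excess in the corner of the Takara chip, both tests of the LC-sense DNA value table and the test of spot-to-spot noise.

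Some control spots passed the filter on dim spots in the Cy3 channel. They were taken as negative controls by name, and whether all were meant to stay dark was not checked. On the Takara chip 8 of 16 negative control spots were above background in Cy3, 4 of 4 lambda-A spots, 3 of 4 lambda-B spots and 1 of 4 Arabidopsis spots, and none was in Cy5. The lambda spots' median signal over background was no lower in Cy5 (1.33 and 1.36) than in Cy3 (1.24 and 1.26). On the LC-sense DNA chip 4 of 80 control spots were above background in Cy3, all of them vector spots, and none of the 68 empty spots was.

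Of the 43 Takara genes with ratios past 2-fold on the A549 side, 20 lay in the first 6 rows of the first sub-grid, 29.9% of the 67 genes there against 4.41% of the 521 genes elsewhere. Genes elsewhere drawn at the same mean intensities gave a median of 3 such calls (95% range 0 to 7), fewer than in the corner. These rows were singled out because calls crowd there, which favours such a gap. The draws did not match each channel by itself. The comparison therefore cannot exclude dim signal in 1 channel. Uneven signal in that corner and a true excess of A549 genes among those spotted there stay open. The 16 genes of the corner that were also on the LC-sense DNA chip had a Takara minus LC-sense DNA difference 0.0056 above the 149 others (95% interval −0.48 to 0.61), and their LC-sense DNA ratios lay 0.13 higher (−0.27 to 0.32), against a Takara excess of 0.21 (−0.77 to 1.12), so these genes are too few to decide. Of the 5 corner calls measured on the LC-sense DNA chip 1 was past 2-fold there, and of the 7 calls elsewhere 4 were. Their median ratios there were 0.21 and 1.03, against 1.17 and 1.23 on the Takara chip. Median Cy5 signal was 365 in the corner and 211 elsewhere, and median Cy3 signal was 1120 and 1316. Spots above background in Cy5 only numbered 9 in the corner and 5 elsewhere.

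The deposited ratios of the LC-sense DNA chip ran opposite to those of the Takara chip. That table correlated with the scanner ratio of A549 over WI38VA13 at r = −0.999, which is consistent with a ratio formed as WI38VA13 over A549. An exchange of the scanner files of the 2 dyes is argued against by the positive correlation of the scanner ratios of both chips, r = 0.61 (95% interval 0.50 to 0.70). No biological explanation was tested.

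Ratios of shared genes differed between the chips by more than replicate spots did. Over the 82 brighter shared genes the SD of the difference was 0.53 (95% interval 0.40 to 0.65), above the 0.28 combined from replicate spots of both chips. This argues against spot-to-spot noise of that size alone. The 0.28 rests on 8 Takara genes and 5 LC-sense DNA genes and has no interval, so noise of other genes may be larger. Dim signal stays open, as r over brighter genes exceeded that over dimmer ones by 0.17 (95% interval −0.10 to 0.40). The corner of the Takara chip also stays open as a part of it, with r = 0.62 over the genes outside. Probes that bind different transcripts were not tested, and no biological explanation was tested because the labels name 1 RNA sample per line.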

How the results depend on the processing

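The alternatives without the first 6 Takara rows, with loess within each sub-grid and with deposited values not centred were chosen after seeing the data. Counts at 2-fold on the Takara chip (70, 43 higher in A549, 27 higher in WI38VA13) were 128, 54 and 74 with the local background subtracted, 33, 24 and 9 with no background correction, and 66, 20 and 46 with the array median in place of loess. They were 17, 10 and 7 at 3-fold, 184, 106 and 78 in the deposited table centred on its median, 191, 50 and 141 in that table not centred, and 46, 23 and 23 without the first 6 rows, and 15 were higher in WI38VA13 when both channels had to be above background. On the LC-sense DNA chip (14, 7 and 7) they were 9, 4 and 5 with no background correction, 21, 13 and 8 with the array median, 4, 1 and 3 at 3-fold, 36, 13 and 23 in the deposited table turned and centred, and 70, 4 and 66 in it turned and not centred. On the LC-sense 5K chip 3-fold left 361 features, 127 positive and 234 negative, and single arrays gave 856 to 881. Features of 1 direction on both arrays were 81.6%, 84.2% with values not centred and 99.0% among features 2-fold apart on either, where r was 0.977.

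List medians on the Takara chip that moved by more than the spot SD were, with the local background subtracted, 1.24 for epithelial, −1.76 for fibroblast and matrix, 1.03 for p53 target and −0.45 for interferon genes. With the array median they were −1.34 for fibroblast and matrix, 0.87 for NRF2 target, −0.44 for cell cycle, 0.29 for cytokine, −0.26 for growth factor receptor, −0.19 for integrin, −0.25 for protease and −0.93 for glycolysis genes. Interferon genes had 0.15 with loess within each sub-grid and −0.46 without the first 6 rows, where cytokine genes had 0.11. On the LC-sense DNA chip the array median gave −0.47 for cytokine, −0.29 for protease and −0.31 for glycolysis genes. Percentiles stayed on their side of the outer limits under these settings, apart from cytokine genes without the first 6 rows (84.3) and growth factor receptor genes on the LC-sense DNA chip with loess within each sub-grid (98.2). Gene lists were not run on the deposited tables. ACTB and GAPDH turned sign in the Takara table after centring (0.31) and not without it (−0.15).

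Of 36 named Takara genes past 2-fold, 13 fell under it with no background correction, 7 in the deposited table centred and 4 not centred, 5 with the array median and 3 with loess within each sub-grid, and of 14 on the LC-sense DNA chip 5, 1, 3, 1 and 2 did. None of them changed sign under any alternative run for single genes. The correlation between the chips ran from 0.54 with no filter to 0.62 without the first 6 rows. The brightest probe per gene was not run because no gene had several probes, nor were LC-sense 5K alternatives that need gene names. No paired analysis was possible because there is 1 RNA sample per line. The cause was not tested for any change, beyond the genes left out by a stricter filter or threshold. Low signal over background on the Takara chip, 1.26 in Cy3 and 1.47 in Cy5, limits what it can show.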
